A study of Mus musculus with 32 samples.

How the data were processed

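The data were 28 single-cell libraries and 4 libraries of 10 cells from mouse subventricular zone at postnatal day 21. Per the submitters' processing notes, reads were processed with TopHat 1.41 and Cufflinks 2.02 on build mm9, and the authors deposited 1 table of FPKM (fragments per kilobase of transcript per 1000000 mapped fragments) per gene. The loci in the table match GRCm38 in place of mm9: 96.0% of its 39011 lines carry a gene ID of GENCODE M21, and 99.8% of those overlap the GRCm38 gene, so coordinates are given as GRCm38. The read layout, strand setting and annotation release are not given in the sources used here.

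Lines of one symbol were summed, giving 38740 symbols. In 27 lines the symbol had been turned into a date and was restored from the gene ID. An exact 0 in the table can be a failed estimate: mt-Co1 was listed at 0 in all 32 libraries, Ttr in 14 and Ptgds in 18. Such genes are described as listed at 0. No 2 libraries held identical values. Genes that share sequence with copies or pseudogenes, such as Eef1a1, Rpl13a and Tpt1, and overlapping or antisense genes are uncertain.

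Depth was estimated from FPKM times length among 2342 genes of 1 exon and 1 transcript of at least 800 bp. An assumed fragment length of 200 bp was subtracted from each length. The most frequent value in a library was taken as the step of 1 fragment, though it need not be the smallest. Several lengths were tried and this one was kept after the steps had been seen, so the depths are approximate.

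A gene was called found at FPKM of at least 1. Per gene, log2((mean FPKM of pools + 1)/(mean FPKM of cells + 1)) was taken, on a scale that understates changes of low genes. For 33 lists with 419 entries, fixed before the data were examined, the median ratio was set among 10000 random lists matched on mean FPKM in 20 bins, and coherence was the mean pairwise Spearman correlation over cells, set among random lists matched on mean FPKM and number of cells. Tubb3, Lhfpl3, Hbb-b2, Gins2 and Cox4i1 were not analysed here. Shares of cells carry exact Clopper-Pearson 95% intervals, and a count of 0 allows 3 of 28 cells. Cells were clustered by Ward linkage on the 1000 genes of largest excess variability over a lowess trend, with 2 to 6 clusters by mean silhouette. In-silico pools were the means of 10 cells drawn 1000 times. No doublet caller was run and no doublet was removed. No test of a difference between cells and pools was made, since cells are not replicates and the pools have no counterpart group.

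The named genes followed a rule fixed before the data were examined: 14 genes always named, the 4 most abundant members of each list and those found in no cell, the 10 largest ratios in each direction with all 4 pools on one side, the 10 most variable genes, the 10 leading genes per cluster, and the 10 most abundant genes.

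Several choices were made after the data were seen. Genes dominated by 1 library were seen to recur at a low level in the other libraries of 2 sets (cells 18 to 22 and 23 to 28), and an alternative was added in which values under 2% of the gene's highest value in the set were put at 0. Cells were joined into a set where such genes of each cell were above 0 in the other at a mean share of at least 80%. The limit of 2% was chosen to lie above the 95th percentile of those low values, and limits of 1% and 5% were also run. The clustering was repeated in 15 added ways. In 12 of them the number of clusters was left free, and 5 of these gave 2 clusters, 4 gave 3 and 3 gave 6. A clustering of 3000 protein-coding genes was at first considered as an account of cell types. It was 1 of 5 protein-coding clusterings without the limit, and the only one of these with 6 clusters, the largest number allowed. It was set aside, since the choice rested on the outcome, and cell types were read per cell from the fixed lists. The tests of explanations in the closing part were written after the results had been seen, and were revised more than once after their values were known. The first version used that clustering, and its bounds were partly written around the values. Later changes replaced a test of leak that its setting could hardly move, set cells 18 to 20 apart by their deposited microglial values after a grouping that had used the limit, marked as undecided a test whose housekeeping control failed, and added the neural stem cell list to the account of Prom1.

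The computations were tested on simulated data, made by shuffling each of 19783 genes over the libraries and planting effects. In a first run recovery was low. Larger sizes were then added, the planted clusters were changed to marker-like genes, and the number of draws was raised to 5. For list ratios, 10 to 15 of 16 lists were recovered at 4-fold and 16 of 16 at 16-fold, with 3.5% to 5% of 200 unchanged lists outside percentiles 2.5 to 97.5 at 4-fold. Shuffling each gene on its own removes correlation between genes, so that rate holds only for lists of unrelated genes. The per-gene shift came out at 1.94 to 1.96 for a planted 2 on the log2 scale. For coherence, 8 to 11 of 16 weak modules and 16 of 16 strong ones were recovered. For 3 planted clusters with 200 genes each, the 1000-gene clustering reached an adjusted Rand index of 0.178 to 0.800, and with 600 or 1200 genes each 0.470 to 1, so it can miss real clusters; a clustering of 3000 genes reached 0.891 to 1 at 200 genes each and 1 at the larger sizes. For variability, the excess rose for 82% to 83.5% of genes given the smaller added spread and 86.5% to 91% at the larger.

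Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, statsmodels 0.14.6 and matplotlib 3.10.9 were used. Alternatives covered the detection limit, pseudocount, scaling, low-value filters, duplicate symbols, each pool left out and the cells with few genes. List medians covered only members at FPKM of at least 1 in a library used, so members could drop out under an alternative.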

Results

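RNA was profiled from the subventricular zone of the mouse forebrain, a zone of postnatal neurogenesis, at postnatal day 21. The series held 28 libraries made from 1 cell each and 4 libraries made from pools of 10 cells. The labels named no animal, sort or treatment, so the 28 cells stood as 1 sample of cells and no p-value was made from them. Values are FPKM, and depth is known only roughly: a step of 1 fragment was clear in 20 of the 32 libraries and placed their depth at about 5.90 to 39.4 in units of 1000000 fragments. Of these libraries, cells 18, 19 and 22 had the highest depths, at 39.4, 30.7 and 39.4. Single cells had a median of 4986 genes with FPKM of at least 1 (range 2107 to 10169), and the pools had 11939 ± 1041 (SD, n = 4).

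**Figure D1:**
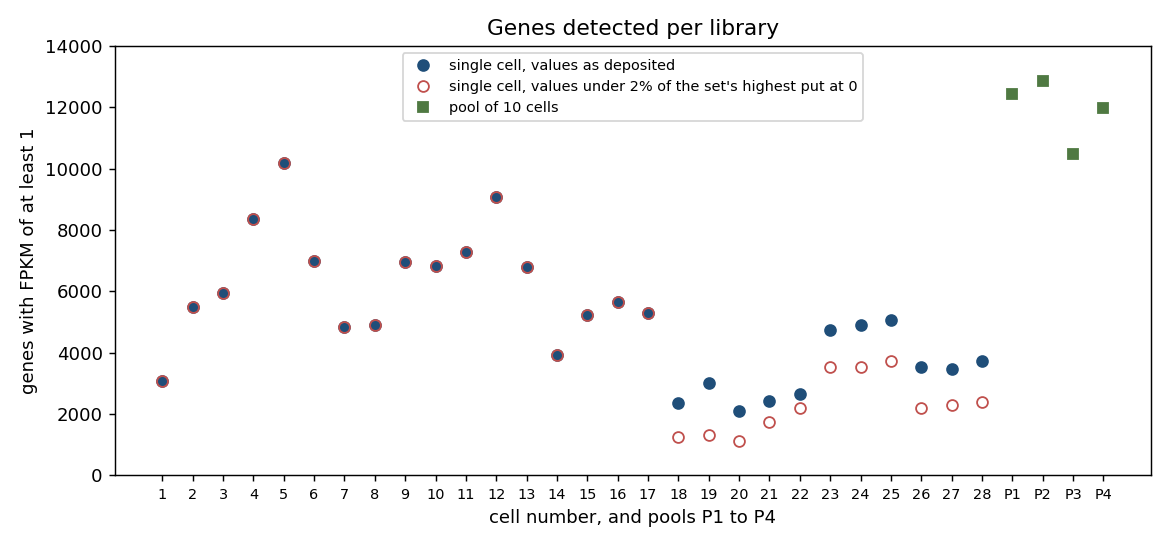
Genes with FPKM of at least 1 (y axis) in cells 1 to 28 and pools P1 to P4 (x axis), as deposited (filled) and with values under 2% of the highest value of the gene in the same library set put at 0 (open). Cells 18 to 28 lost genes under that limit, for example from 3020 to 1329 in cell 19, and the pools lay between 10478 and 12870.

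The 28 cells were first described by marker lists fixed before the data were examined. Endothelial markers led 8 cells (cells 1, 2, 3, 6, 7, 8, 16 and 17), each of which had 9 to 12 of the 12 markers, among them Cldn5, a tight junction protein of brain vessels, and Ly6c1. Oligodendrocyte markers such as Mbp and Mobp, which encode myelin proteins, led cells 4, 12 and 13, each with 10 of 11. Markers of motile cilia led cells 9 and 15 with 15 and 14 of 18, and astrocyte markers such as Slc1a3, a glutamate transporter, led cells 11 and 14 with 13 and 12 of 14. The astrocyte list also covers astrocyte-like stem cells, so it cannot tell these types apart. Of 12 neural stem cell markers, cell 11 had 8 and cell 14 had 4. Microglial markers, among them the complement genes C1qa and C1qc, led cells 18, 19 and 20 with 11, 12 and 10 of 12.

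The remaining cells were less uniform. Choroid plexus markers led cell 5 with 9 of 10, beside 10 of 18 ependymal markers. Cell 10 was led by the neural stem cell list with 8 of 12, beside 11 of 18 ependymal markers. Cell 3 had 10 of 12 microglial markers beside all 12 endothelial ones. Neuroblast markers such as Dcx, a microtubule protein of migrating neuroblasts, led cells 22 to 26 and cell 28, with 8 to 11 of 13 in each. Cells 21 and 27 were led by the microglia list at lower means, 4.64 and 2.86 in log2(FPKM + 1), with 11 and 4 of 12 markers. They also had 8 and 7 of 13 neuroblast markers, at means of 3.20 and 2.48. Of 12 mature neuron genes, Rbfox3, Slc17a7, Slc17a6, Drd1a and Drd2 were at FPKM of at least 1 in no cell, Snap25 was in 18 cells, and the most in 1 cell were 4, in cell 12.

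The cells led by microglia and neuroblast markers all lay in 2 sets of libraries that shared a technical trait. In cells 18 to 22, genes with at least 500 FPKM in 1 cell and under 5% of that in the others of the set were above 0 in 98.7% of the other libraries of the set, at a median of 0.336% of the highest value, and reached FPKM of 1 in 85.5%. In cells 23 to 28 the same shares were 97.6% and 79.7%, against 15.1% and 6.16% in the other 17 cells. The sets were defined by this trait, so high shares within them follow in part from the definition. Of these genes, 107 and 123 also stayed under 5% of the highest value in every cell outside the set, and they were above 0 in 36.5% and 31.8% of the values there. Processed pseudogenes made up 0.0826% to 0.268% of FPKM in cells 18 to 22 and at least 5.002% in the other cells, and the small RNA Gm23134 made up over 10% in cells 23 to 28 and in cell 15. With values under 2% of the set's highest put at 0, a limit chosen after the data were seen, cell 21 was led by neuroblast in place of microglial markers, with 5 of 13. Cells 22 to 26 and cell 28 then had 6 to 9 of 13 neuroblast markers, the fewest in cell 26. Cell 27 stayed led by the microglia list, with 3 of 12, at a mean of 2.60 against 1.79 for the neuroblast list.

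**Figure D2:**
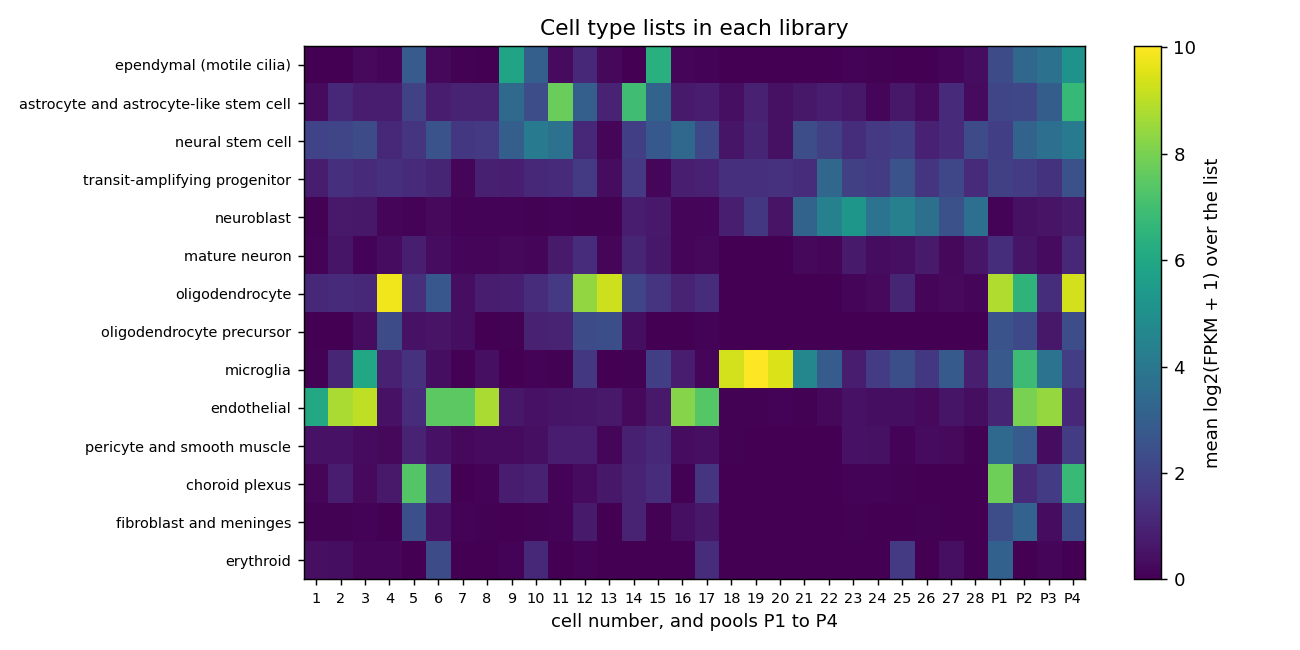
Mean log2(FPKM + 1) of each of the 14 cell type lists (y axis) in cells 1 to 28 and pools P1 to P4 (x axis), as deposited. Endothelial markers stand out in 8 cells and in pools 2 and 3, and microglial markers in cells 18 to 20.

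The series title concerns dormant neural stem cells, so markers and receptors of stem cells were counted next. Prom1, a surface protein used to mark neural stem and ependymal cells (chromosome 5, 43993625 to 44102032, GRCm38), was at FPKM of at least 1 in 11 of 28 cells, or 39.3% (95% Clopper-Pearson interval 21.5% to 59.4%). These were the 8 cells led by endothelial markers, at 72.4 to 534 FPKM, and cells 4, 9 and 10, at 9.41, 86.4 and 70.6 FPKM. Gfap, an intermediate filament of astrocytes and stem cells, was found in 6 cells (21.4%, 8.30% to 41.0%), and Foxj1, a regulator of motile cilia, in 4 (14.3%, 4.03% to 32.7%). Egfr, a receptor of activated progenitors, was found in 3 cells and Mki67, a proliferation gene, in 3 (each 10.7%, 2.27% to 28.2%). Sox2 was found in 18 cells (64.3%, 44.1% to 81.4%), a number that fell to 13 under the 2% limit; the counts of the other 13 genes always named did not change under it.

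Receptors of vascular growth factors ran with Prom1 in the cells led by endothelial markers. Flt1 was found in 8 cells, all of which had Prom1, Kdr in 11, of which 9 had Prom1, and Flt4 in 4, all with Prom1. The 8 Flt1 cells were the 8 led by endothelial markers. These also held all 4 Flt4 cells and, apart from cell 10, all cells with both Kdr and Prom1. S1pr1, a sphingosine-1-phosphate receptor, was found in 10 cells, and its highest values, 912, 751 and 734 FPKM, were in cells 11, 8 and 14. Nes was found in 9 cells, Fgfr1 in 8, and Ptgds, a prostaglandin D synthase, in 7.

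Prom1 and Gfap were found together in cells 4, 9 and 10, as were Prom1 and Foxj1 (3 cells each). Foxj1 and Gfap shared 4 cells, Foxj1 and Nes 2, S1pr1 and Gfap 2, and Gfap and Egfr 1. No cell had both Gfap and Dcx, or both Egfr and Mki67, for which the exact interval reaches 12.3% and the floor of 3 of 28 cells is 10.7%. Intervals and floors cover counting error only. Among 18 genes not expressed in brain, 4 pairs of gene and cell (0.794% of pairs) reached FPKM of 1.

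**Figure D3:**
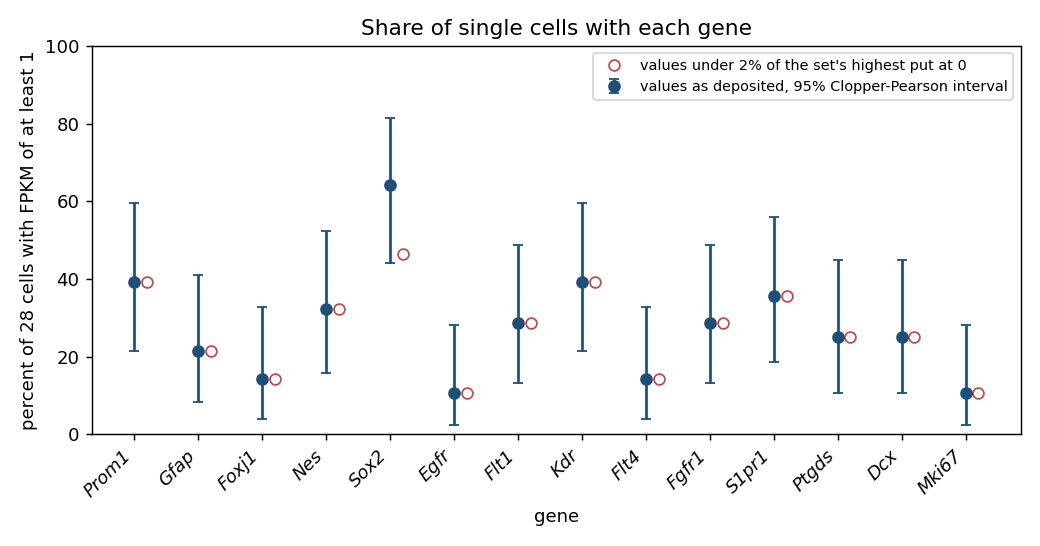
Percent of the 28 cells with FPKM of at least 1 (y axis) for the 14 genes always named (x axis), with 95% Clopper-Pearson intervals, and the percent with values under 2% of the set's highest put at 0 (open). Only Sox2 moved, from 64.3% to 46.4%.

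Genes of several cell type lists varied together from cell to cell. Among lists of more than 3 genes, endothelial genes had the highest value, with a mean pairwise Spearman correlation of 0.684 over the 28 cells, followed by oligodendrocyte genes (0.612), neuroblast genes (0.555) and ependymal genes (0.531), each at percentile 100 among matched random lists. G2 and M phase genes (0.497), immediate early genes such as Fos and Egr1 (0.406) and astrocyte genes (0.393) were also at percentile 100, and microglial genes had 0.485 at percentile 99.99. A set of 3 oligodendrocyte precursor genes had 0.653. The neural stem cell list had 0.0918, at percentile 50.2, and the transit-amplifying list -0.0705, at percentile 2.94. Under the 2% limit the neuroblast value was 0.333 (percentile 99.87), and the G2 and M phase value 0.381 (99.35) on 6 genes in place of 11. Without cells 18, 20 and 21, which had few detected genes, the G2 and M phase value was 0.243. Of all cells, cell 21 had the highest mean of that list.

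Of the signalling and metabolic lists, interferon and antigen presentation genes had 0.287 (percentile 99.99), growth factor receptors 0.321 (99.69), VEGF signalling 0.308 (99.12), and oxidative phosphorylation genes 0.237 (99.31). Glycolysis had 0.214 (98.69), sphingosine-1-phosphate and prostaglandin genes 0.269 (98.47), and extracellular matrix genes 0.217 (97.61). Within the 17 cells outside the sets the values were 0.284 for interferon (percentile 99.99), 0.268 for growth factor receptors (97.98) and 0.136 for VEGF signalling (81.5). Oxidative phosphorylation had 0.124 there (99.07) and glycolysis 0.184 (99.97). Sphingosine-1-phosphate and prostaglandin genes had -0.0102 there (25.99), and extracellular matrix genes 0.000292 (15.36). BMP signalling had 0.195, fatty acid oxidation 0.185, Wnt signalling 0.177, cell cycle inhibitors 0.122, mature neuron genes 0.121, Notch signalling 0.0987, fibroblast genes 0.0941, S phase genes 0.0819 and housekeeping genes 0.0359, at percentiles from 7.57 to 94.76. Hedgehog and choroid plexus genes, on 3 genes each, had 0.368 and 0.324. Pericyte, erythroid, control and sex-linked genes were found in too few cells for a value.

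Clustering on the 1000 most variable genes gave 3 clusters with a mean silhouette of 0.171. They held cells 1 to 17, cells 18 to 22 and cells 23 to 28. Cells 1 to 17 were led by Ly6c1 and Ly6a, and cells 23 to 28 by small RNAs, a pseudogene and the unclassified Gm22574. Cells 18 to 22 were led by small RNAs and by the protein-coding genes Serpinf1, Gp9, Crybb1, Ccl6, P2ry6, Fcrls and Olfml3. Fcrls was at FPKM of at least 1 in 7 cells as deposited and in 5 under the 2% limit. The others of these protein-coding genes were in 5 cells as deposited. Under the limit Serpinf1 and Ccl6 were in 2, Olfml3 in 3, and Gp9, Crybb1 and P2ry6 in 1. Clusters 2 and 3 were the 2 library sets described above, so no cluster was given a cell type name, and library set and cell type cannot be told apart in them. The 10 genes of largest excess variability were small RNAs and Gm17571, and 2 of the 10 were named again under the 2% limit.

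Pools of 10 cells were then compared with single cells. Neuroblast genes were lower in the pools: the median log2 ratio of pools over cells was -3.43 (SD over pools 0.871, n = 4), with 13 of 13 genes lower. Dcx had -5.57 and was below FPKM of 1 in all 4 pools, Gad2 had -5.70, and Dlx6os1 was listed at 0 in all 4 pools against 11 cells with the gene. G2 and M phase genes had -3.12 (SD 0.904), with 13 of 13 measured genes lower, among them Birc5 at -6.48, and microglial genes -2.96 (SD 2.11, -5.10 without pool 2), with 10 of 12 lower. All 3 lists lay at percentile 0 among matched random lists. Genes of a random list need not vary together as markers of 1 cell type do, so that percentile overstates how unusual the lists are. In-silico pools drawn from the cells set the lists apart. The microglia mean of the draws was at or below pools 1 to 4 in 7%, 29.4%, 12.9% and 1.8% of draws. For the G2 and M phase list these shares were 3.2%, 10%, 7.5% and 45.9%, and for the neuroblast list at most 0.1%. Housekeeping genes lay below every draw in pools 1, 3 and 4, so these shares are uncertain.

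The neuroblast and microglia lists were highest in cells of the 2 library sets, and the G2 and M phase list in cell 21 of 1 set. Against the 17 other cells the neuroblast, G2 and M phase and microglia ratios were 0.18, -0.52 and 1.61. These medians covered only list members at FPKM of at least 1 in those cells or in a pool, so Dcx left the neuroblast list. No cell of the 17 was led by neuroblast or microglial markers, so a deficit in the pools could hardly show against them. The G2 and M phase genes Birc5, Ube2c, Cenpa and Top2a had their highest value in cell 21. The list mean was 7.07 there as deposited and 6.91 under the 2% limit. Under that limit cells 18, 19, 20 and 22 had 0, 1.12, 0.44 and 0, and cells 23 to 28 had at most 0.38 as deposited. Without cells 18, 20 and 21, which had few detected genes, the G2 and M phase ratio was -0.38, but this also removed cell 21. By means of log values, where the median of all genes was 0.95, the neuroblast, G2 and M phase and microglia ratios were -0.80, 0.060 and 1.48. Relative to that median they were -1.76, -0.90 and 0.52.

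Other lists were higher in the mean of the pools. Pericyte and smooth muscle genes had a ratio of 2.94 (SD 1.04), with 10 of 10 genes higher, but the median over the genes was 1.67 and 1.91 in pools 1 and 2 and 0 in pools 3 and 4, and without pool 1 the ratio was 1.23. Acta2 had 1159 FPKM in pool 1 and at most 172 in the others, and Vtn had 413 in pool 2 and at most 35.1 in the others. Choroid plexus genes had 2.17 (SD 3.21), with Ttr, a thyroid hormone carrier, at 33894 and 19813 FPKM in pools 1 and 4 and at 19.5 and 25.1 in pools 2 and 3; the list ratio was -3.01 and -2.01 in pools 2 and 3 and 0.97 without pool 1. Oligodendrocyte genes had 1.47 (SD 3.96), with -6.15 in pool 3 and 0.73 without pool 1. The oligodendrocyte precursor list had 1.14 (SD 0.612, -0.37 in pool 3, 0.54 without pool 4), the fibroblast list 0.92 (SD 0.818, at or below 0 in pools 1, 3 and 4, 2.17 without pool 2) and the erythroid list 1.18 (SD 2.34), the last -1.48 without pool 1. The fibroblast value without pool 2 is over fewer genes, since members found only in pool 2 then left the list. It is thus no sign of a higher ratio in the other pools. Oxidative phosphorylation genes had 0.32 (SD 0.236), with 16 of 18 higher and 0.12 to 0.61 in the 4 pools. Under upper quartile scaling the median of all genes shifted to -1.67 and the oxidative phosphorylation ratio to -3.09, or -1.42 relative to that shift; rescaling every library to the same sum shifted all genes to 0.24.

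The pools differed among themselves in kind. Pools 1 and 4 were led by oligodendrocyte markers (8.84 and 9.36 in mean log2(FPKM + 1)) and then choroid plexus markers (7.81 and 6.80), and pools 2 and 3 by endothelial markers (8.01 and 8.45). Prom1 was at 211 and 241 FPKM in pools 2 and 3, 1.30 in pool 4 and 0.0345 in pool 1, and Flt1 at 211, 405, 0.0332 and 0.361 in the same order. The endothelial list had a ratio of 0.38 with an SD over pools of 3.80, and of -0.46 to 0.79 with 1 pool left out. In-silico pools, each the mean of 10 cells drawn from the 28, had a median neuroblast mean of 3.76, against 0.098, 0.46, 0.54 and 0.72 in pools 1 to 4. Their median endothelial mean was 6.96, against 1.03 and 1.10 in pools 1 and 4. Housekeeping genes lay below every in-silico pool in pools 1, 3 and 4, at 8.78, 7.79 and 7.47 against a lowest draw of 8.82. The pools also differed in a technical measure. Processed pseudogenes made up 9.94% and 13.2% of FPKM in pools 1 and 2 and 3.06% and 1.85% in pools 3 and 4. Whether this bears on the differences among the pools was not tested.

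**Figure D4:**
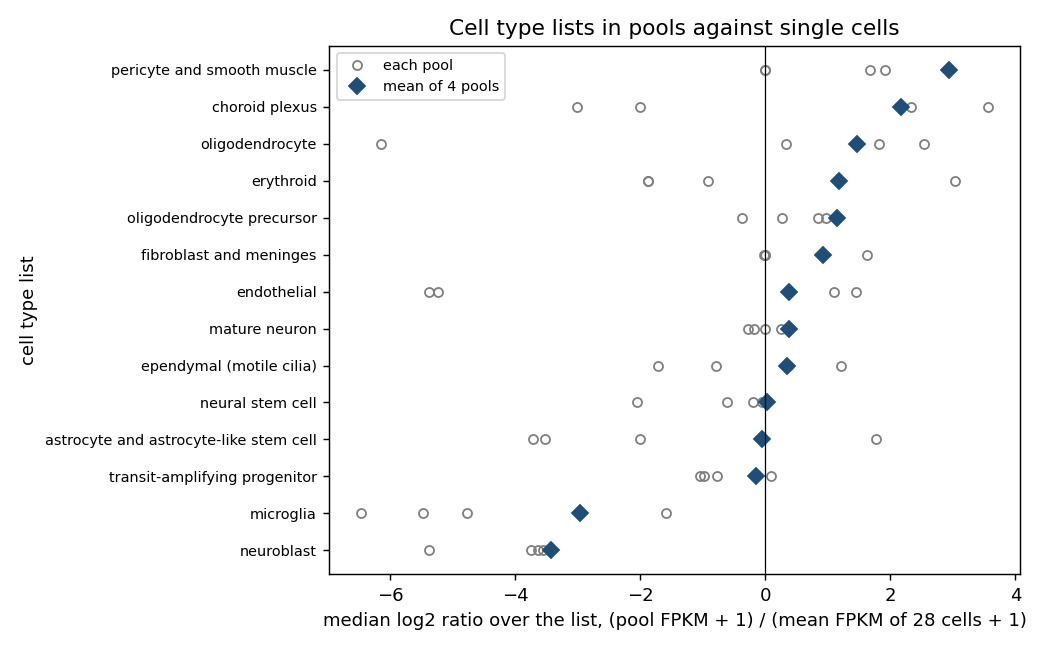
Median log2 ratio of (pool FPKM + 1) over (mean FPKM of the 28 cells + 1) for each cell type list (y axis), for each pool (open circles) and for the mean of the 4 pools (diamonds). The neuroblast list lies at -3.43 with the pools from -5.38 to -3.56, and the pericyte list at 2.94 with pools 3 and 4 at 0; the diamond is the median over genes of the ratio of the mean pool, so it can lie above every circle.

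The remaining lists had ratios between -0.24 and 0.66. In the main setting the ratios were ependymal 0.34, astrocyte -0.054, neural stem cell 0.030, transit-amplifying -0.14, mature neuron 0.37, control genes 0.66, housekeeping -0.24, immediate early 0.12, S phase -0.095 and cell cycle inhibitors 0.13. VEGF signalling had 0.19, growth factor receptors 0.27, sphingosine-1-phosphate and prostaglandin 0.39, Notch 0.14, BMP 0.40, Wnt 0.24 and Hedgehog 0.46. With 1 pool left out, the Hedgehog ratio ranged from -0.18 to 0.67. Interferon genes had -0.029, extracellular matrix 0.28, glycolysis 0.15 and fatty acid oxidation 0.19. A value near 0 here need not mean like pools: the astrocyte list had -3.71, -3.51, -2.01 and 1.77 in pools 1 to 4 (SD 2.54). Without pool 4 the astrocyte, neural stem cell, transit-amplifying and ependymal ratios were -2.28, -0.84, -0.78 and -0.18. Without pool 3 the VEGF and immediate early ratios were -0.60 and -0.45, and without pool 2 the housekeeping ratio was -0.75. Among the lists with ratios between -0.24 and 0.66, mature neuron (SD over pools 0.231), sphingosine-1-phosphate and prostaglandin (0.324) and BMP (0.338) exceeded their SD. In single pools the mature neuron list was above 0 only in pool 1 (0.25), the sphingosine-1-phosphate list had -0.14 in pool 1, and the BMP list had -0.29 and -0.36 in pools 1 and 2. The mature neuron ratio was -0.041 without pool 2 and the BMP ratio -0.013 without pool 3. Relative to the shift under upper quartile scaling these 3 were -0.92, 0.50 and 0.030. Of the sex-linked genes, Xist was found in 13 cells and Uty in 1.

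Among 8734 genes with mean FPKM of at least 10 in either group, all 4 pools lay above the mean of the cells for 436 and below it for 2117. The largest ratios among protein-coding genes with all pools above were those of Chmp6 (4.10), Zfp37 (3.82), Parp4 (3.52), Slc1a5 (3.22) and Gnl3 (3.19), each found in 2 or 3 cells. Each was highest in pool 1 or pool 2: Chmp6 had 15.3 and 69.1 FPKM there against 0.736 and 0.691 in pools 3 and 4. With 1 pool left out, the lowest ratios of these genes were 2.33, 1.14, 2.09, 1.69 and 1.21, in the order above. Under upper quartile scaling, Slc1a5 had 0.96. The 10 lowest were small or predicted RNAs such as Mirlet7b, listed at or near 0 in the pools. Against the 17 cells outside the library sets, 6 of these 10 had ratios within 0.01 of 0, Mirlet7b among them, and the other 4 had -8.61 to -2.96.

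Across genes, which are not independent replicates, log2(FPKM + 1) profiles of 2 cells correlated at a median of 0.427 (range 0.197 to 0.748, 378 pairs) and those of 2 pools at 0.748 (0.699 to 0.800, 6 pairs). The mean of the cells correlated with the mean of the pools at 0.920. The in-silico pools had a median of 12249 genes, against 12439, 12870, 10478 and 11970 in the 4 pools, and correlated with them at medians of 0.786, 0.799, 0.768 and 0.754.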

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

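In a group of 4 pools, a value was singled out when its gap to the nearest pool exceeded the 95% critical share of the range. Of 45 groups examined 3 were singled out, and chance gives about 2.25. The mean log2(FPKM + 1) of the oligodendrocyte precursor list was low in pool 3, at 0.63 against 2.56, 2.23 and 2.39, a ratio of 0.82905. The erythroid list was high in pool 1, at 3.11 against 0, 0.19 and 0, a ratio of 0.938. S1pr1 was low in pool 1, where it was listed at 0, against 6.50, 6.64 and 7.79 in log2(FPKM + 1), a ratio of 0.834. No explanation was tested for these values.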

How the results depend on the processing

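Alternatives with leaked values at 0, with the 17 cells outside the library sets, or with protein-coding genes were chosen after the data were seen; the others were planned. No paired analysis was possible because the results come from no test and the replicate numbers name libraries only. The cause of the changes below was not tested, except that upper quartile scaling divides by values from 0.119 to 26.2 in cells and from 22.7 to 31.4 in pools and so raises cells with few genes. Of the alternative values of the main results, 591 stayed within the limit set for that kind of result, 101 moved further and 10 were labelled reversed. For list ratios, a sign change was labelled reversed only where the main ratio exceeded its SD over pools. The 10 are thus not all the sign changes, and others lie among the 591 and the 101. Under upper quartile scaling, for example, the ependymal ratio went from 0.34 to -0.72 (among the 591). The glycolysis ratio went from 0.15 to -3.31 there (among the 101).
At FPKM above 0, values were genes detected in the median of single cells 10559, genes detected in the mean of pools 16706, Gfap 46.4%, Nes 57.1%, Sox2 92.9%, Egfr 82.1%, Flt1 75%, Kdr 67.9%. There too, Flt4 35.7%, Fgfr1 67.9%, Dcx 100%, Mki67 57.1%, Prom1 and Gfap 42.9%, Prom1 and Foxj1 28.6%, Gfap and Egfr 46.4%, Egfr and Mki67 39.3% were found. Further values were Gfap and Dcx 46.4%, Kdr and Prom1 53.6%, Flt1 and Prom1 57.1%, Flt4 and Prom1 35.7%, S1pr1 and Gfap 39.3%. At FPKM of at least 5, values were genes detected in the mean of pools 8274, in-silico median genes detected 8508. Over genes with mean FPKM of at least 1, values were correlation of mean of cells with mean of pools 0.788, correlation of median of pairs of pools 0.547, mature neuron 0.079, fibroblast and meninges 2.021. Under upper quartile scaling, values were correlation of mean of cells with mean of pools 0.821, astrocyte and astrocyte-like stem cell -3.06, neural stem cell -1.95, transit-amplifying progenitor -2.40, neuroblast -8.87, mature neuron -2.59, oligodendrocyte precursor 0.26, microglia -10.28. Others were pericyte and smooth muscle 0.91, housekeeping -5.23, immediate early and stress -5.65, S phase -1.30, G2 and M phase -9.42, cell cycle inhibitors -2.47, sphingosine-1-phosphate and prostaglandin -1.17, Notch -2.10. Beside these came BMP -1.64, Wnt -1.25, interferon and antigen presentation -3.16, extracellular matrix and adhesion -2.16, glycolysis -3.31, oxidative phosphorylation -3.09, fatty acid oxidation -3.40, all genes -1.67. Over the 17 cells outside the sets, values were correlation of mean of cells with mean of pools 0.954, neuroblast 0.18, oligodendrocyte precursor 0.45, microglia 1.61, G2 and M phase -0.52, sphingosine-1-phosphate and prostaglandin 0.064, BMP 0.018, extracellular matrix and adhesion -0.26. There too, log2 ratio of Mir3064 1.59e-08, all genes -0.063, coherence of sphingosine-1-phosphate and prostaglandin -0.0102, in-silico median genes detected 13253, in-silico median correlation with a pool 0.83 were found. By Spearman correlation, values were correlation of median of pairs of cells 0.599. By means of log2(FPKM + 1), values were ependymal (motile cilia) 3.32, neural stem cell 1.39, transit-amplifying progenitor 0.43, neuroblast -0.80, microglia 1.48, pericyte and smooth muscle 1.57, immediate early and stress 2.495, S phase 1.13. Further values were G2 and M phase 0.060, cell cycle inhibitors 1.96, FGF, EGF, PDGF and IGF receptors 1.28, sphingosine-1-phosphate and prostaglandin 0.98, Notch 0.996, BMP 1.91, interferon and antigen presentation 2.49, extracellular matrix and adhesion 1.87. Others were glycolysis 2.66, oxidative phosphorylation 3.15, fatty acid oxidation 2.35, log2 ratio of Mki67 0.019, all genes 0.95. At a pseudocount of 0.1, values were neuroblast -4.57, mature neuron 0.86, fibroblast and meninges 2.64, not expressed in brain (control) 1.64. At a pseudocount of 5, values were neuroblast -2.54, mature neuron 0.094, oligodendrocyte precursor 0.31, pericyte and smooth muscle 1.33, G2 and M phase -1.96. Without cells 18, 20 and 21, values were G2 and M phase -0.38. Rescaled to a sum of 1000000, values were oxidative phosphorylation 0.65, all genes 0.24. With a leak limit of 5%, values were Sox2 39.3%. With a leak limit of 2%, values were genes shared with the 10 named 2. With 3000 protein-coding genes, 3000 genes under the leak limit, or both, 6 clusters were found. Leaving out 1 pool at a time gave correlation of mean of cells with mean of pools 0.899 to 0.919, transit-amplifying progenitor -0.78 to 0.10, mature neuron -0.041 to 0.52, microglia -5.10 to -2.64, pericyte and smooth muscle 1.23 to 3.32. It also gave fibroblast and meninges 1.13 to 2.17, erythroid -1.48 to 1.55, BMP -0.013 to 0.54, extracellular matrix and adhesion -0.25 to 0.40.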

Other observations

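All tests in this part were chosen only after the result was seen and were revised more than once after their values were known, and no biological explanation was tested, since the design gives no group to set against these patterns.

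Some single libraries held unusual mixtures of markers. Cell 4, led by oligodendrocyte markers, also had Gfap at 25.9, Foxj1 at 3.28 and Prom1 at 9.41 FPKM. Cell 3 had 10 of 12 microglial markers beside 12 of 12 endothelial ones, and cell 6 had 6 of 11 oligodendrocyte markers beside 11 of 12 endothelial ones. Mki67 was found in cells 8, 21 and 25, at 16.1 to 72.1 FPKM, of which cell 8 was led by endothelial markers.

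The 3 clusters of cells were the 2 library sets and the other cells. Cells 18 to 20 were set apart because their deposited microglia mean was at least 2 times that of the next list. Their median microglial marker lay at 67.1%, 74.2% and 60.4% of the set's highest value as deposited, against 0.612% and 0.183% in cells 21 and 22. Those 3 shares lie above the 2% limit for leaked values. They come from the values that chose the cells, so they cannot serve as a test of leak. Cells 21 and 27, also led by the microglia list as deposited, were left out by that choice, and cell 27 lay at 0.515%. Leak could account for the split of the other cells between the sets: with 3 clusters kept and leaked values (under 2% of the set's highest) at 0, 8 of 8 shared a cluster with cells from outside their set, cells 21 and 22 with cells 23 to 27, and cell 28 with cells 1 to 17. Whether they then parted from cells 1 to 17 depended on the choice: cells 21 to 28 all lay with them at the 2 clusters found freely on 1000 genes and all apart from them at the 6 found on 3000, and a limit of 5% put cells 21 to 27 apart and one of 1% cells 26 and 27. With protein-coding genes alone 1 of 11 cells (cell 22) moved at 3 clusters and cells 22 to 28 lay with cells 1 to 17 at the 2 clusters found freely, while average linkage on these genes kept both sets whole, so small RNAs and pseudogenes stay open, and a batch difference cannot be told apart from cell type, since 0 cells of the sets were led by a list that also led a cell outside them.

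The neuroblast list was lower in the pools than in the cells. Leaked reads within a set were examined by the list mean of each cell, not by the ratio of pools over cells. Of the 10 cells of the sets with a list mean above every pool, 8 (cells 21 to 28) stayed above with leaked values at 0. They had 1.79 to 5.12 against at most 0.72 in the pools, while cells 18 and 19 fell to 0.0015 and 0. The limit keeps each gene's highest value in a set, so the outcome was partly fixed in advance. Leak within a set is argued against only as the whole cause of the higher list means of cells 21 to 28. Reads leaked from outside a set were not covered. Of 1000 in-silico pools 0.1% had a list mean at or below that of the highest real pool, but 3 of the 4 real pools also lay outside the in-silico range for housekeeping genes, where draws of these cells should have held them, and the pool inside it, pool 2, lay below every draw at 0.46 but is a single library, so chance stays open. A difference between library sets could not be told apart from cell type: 0 cells outside the sets had 7 or more of the 13 neuroblast markers.

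Prom1 was found in 8 cells with most endothelial markers. A second cell of the ependymal or astrocyte type in the same libraries is argued against, as 0 of the 8 had 9 of 18 ependymal or 7 of 14 astrocyte markers, and the most were 1 and 3. Leaked reads are argued against too, since the lowest Prom1 value in these cells was 13.6% of the highest over the 28 cells. A second cell of the neural stem cell type stays open: 1 of the 8 (cell 16) had 7 of the 12 markers of that list, which holds Prom1 itself, and the others had 2 to 5. Other second cell types were not tested, and cell 3 held microglial markers as well.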
